A study of Homo sapiens with 6 samples.

How the data were processed

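RNA sequencing was done on total RNA of Hep3B cells, a human hepatocellular carcinoma cell line, transfected with control siRNA (si-Cont, 3 libraries) or siRNA against SMARCA4 (si-SMARCA4, 3 libraries). Groups and replicate numbers were taken from the sample titles. The values deposited by the authors were FPKM, that is fragments or reads scaled by gene length and by a denominator per library, for 57773 genes, and the submitters' notes name the hg19 genome build. The aligner, counting program, annotation, strandedness and siRNA sequences are not given in the sources used here.

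Of 25119 genes with a mean above 0, 25114 (99.98%) had values that were whole multiples of 1 read's worth, at a relative tolerance of 1e-08, with 1 gene length and 1 denominator per library. Whole reads were recovered from these steps. They came to 18403241 to 21875021 reads over genes per library, against FPKM denominators of 29138265 to 33822440 reads. Reads without molecular identifiers are not independent molecules, so read numbers speak for counting error only.

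Genes with a mean FPKM of at least 1 over the 6 libraries were kept (11123 genes). Their log2(FPKM + 1) values were compared with limma 3.58.1 in R 4.3.3 (linear fit, moderated statistics with a trend, two-sided), and p-values were adjusted by Benjamini-Hochberg. The threshold was an adjusted p of 0.05. For single genes of interest an exact permutation test, two-sided, was also run, whose smallest possible p with 3 against 3 libraries is 0.1. These p-values measure only the spread between these libraries, since the labels do not say whether the replicates were separate cultures.

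The gene lists (36, of 1043 symbols in all, of which PECAM1 and CD24 were not analysed here) and the rule for named genes were fixed before the data were examined. Lists with at least 5 genes kept (32) were tested with camera of limma at a preset inter-gene correlation of 0.01, with SMARCA4 left out of its own list, and again with a correlation estimated per list. Named genes were SMARCA4, 3 genes of interest (IRAK1, PSMD10 and AKR1B10), the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and the 4 members with the smallest p of each list past the threshold and of 7 lists chosen beforehand, whether past it or not. That rule gave 87 genes, of which 86 were tested and 85 passed the threshold, all 85 with groups that did not overlap; some of these genes are not reported here. Symbols that end in a running number (2250 in the table, such as SDHD_1) are printed as the table gives them.

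Replicate numbers were checked for pairing by correlating each library's deviations from its group mean with those of the other group. Libraries with the same number correlated at 0.215, 0.181 and 0.162, higher than with either other number, so a fit with replicate number as a block was compared with the fit without it. Alternatives were other pseudocounts (0.1 and 5), other filters, median-ratio, upper-quartile and quantile scaling, other limma settings, stricter thresholds, summed rows of 1 symbol, and leaving out each library in turn. Limma voom on the recovered reads, removal of a trend with gene length and GC content together with the replicate block, and a fit without genes whose 3′ UTR holds TGTCCA were chosen after seeing the data.

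Sequences of 7 bases were searched in the 3′ UTRs of the GENCODE v29 annotation on GRCh38, also after seeing the data. For each gene the longest 3′ UTR among its annotated coding transcripts was used. Whether these cells express that transcript was not examined. Of the 11123 genes, 10283 had a 3′ UTR of at least 50 bases, and SMARCA4 was left out, which left 10282. Fold changes were adjusted for 3′ UTR length and GC content. Each of the 16152 sequences present in at least 50 genes was scored as the mean adjusted change of the genes that hold it over its standard error, and the fold changes were shuffled over genes 100 times for comparison. The genes were also parted at random into 5165 and 5117, with the sequences chosen on either part and their carriers compared in the other. Positions on GRCh38 are given only for these sequence matches, since the authors' values were made on hg19. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

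The procedure was tested on simulated data in which known genes were changed. Of 50 genes changed 1.25-fold, 45 (90%) were called, as were all 50, 48 and 44 genes changed 1.5-fold, 2-fold and 4-fold, while 12 of 10883 unchanged genes were called. A planted gene list passed and 0 of 35 random lists did. In that simulation every gene had the same dispersion, values were scaled by the library totals used to simulate them, and no library stood apart. In the real data si-Cont replicate 2 stood apart, so these shares are not error rates of the single-gene calls reported here. The simulated genes also varied independently of each other. The simulation therefore does not test false calls of lists whose members vary together, where the estimated correlation reached 0.863 (ribosomal proteins). Each of 5 planted 3′ UTR sequences was ranked first.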

Results

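The series compares Hep3B cells given siRNA against SMARCA4 (n = 3 libraries) with cells given control siRNA (n = 3 libraries). SMARCA4, also called BRG1, is an ATPase of the SWI/SNF chromatin remodelling complexes. Between 18403241 and 21875021 reads per library lay over genes. The share of the FPKM denominator that lay over genes was 65.4% ± 1.99 (SD, n = 3) in si-Cont and 61.6% ± 0.677 (SD, n = 3) in si-SMARCA4. Reads of the mitochondrial genome took 1.17% in both groups. The first principal component held 83.8% of the variance and separated the groups. The second held 8.58% and set si-Cont replicate 2 (-11.0) apart from the other 5 libraries, which lay between -1.83 and 5.70. The noncoding RNA MALAT1 stood at 401 FPKM in si-Cont replicate 2 and at 288 to 312 FPKM in the other 5 libraries. Measured against counting error alone, the chi-square per degree of freedom was 2.01 to 2.25 between si-SMARCA4 libraries, 2.96 between si-Cont replicates 1 and 3, 8.32 and 9.88 between si-Cont replicate 2 and those replicates, and 37.9 to 45.2 between groups.

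The comparison asks which transcripts differ when SMARCA4 is depleted. SMARCA4 itself (ENSG00000127616) fell from 17.3 ± 1.98 to 3.86 ± 0.128 FPKM (SD, n = 3 each), which is 22.3% of the si-Cont level, with 5687 to 6231 reads per library in si-Cont and 1343 to 1407 in si-SMARCA4. Its log2 fold change was -1.91 (SE 0.07), with a limma adjusted p = 1.63e-08, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. SMARCA2, the other ATPase of these complexes, fell from 3.57 ± 0.165 to 2.15 ± 0.152 FPKM (log2 fold change -0.54). Among the 3 genes of interest, IRAK1 (ENSG00000184216), a kinase of interleukin-1 and Toll-like receptor signalling, fell from 17.4 ± 0.836 to 5.31 ± 0.226 FPKM, or 30.5% of si-Cont (log2 fold change -1.54, limma adjusted p = 1.0e-08, exact permutation p = 0.1). The 3′ UTR of IRAK1 holds the sequence TGTCCAA, whose carriers were lower on average. PSMD10, a proteasome assembly factor, stood at 7.81 ± 0.679 and 8.06 ± 0.606 FPKM (log2 fold change 0.04, limma adjusted p = 0.631). AKR1B10, an aldo-keto reductase, stood at 0.258 and 0.327 FPKM with 14 to 22 reads per library (exact permutation p = 0.3) and lay under the mean FPKM of 1 asked for in the limma fit.

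**Figure D1:**
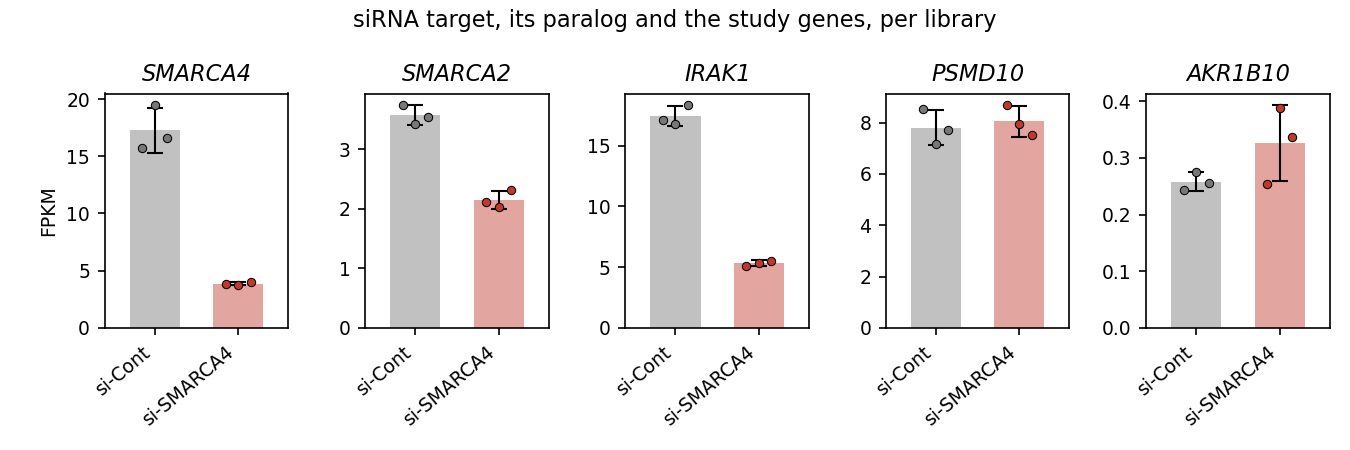
FPKM of SMARCA4, SMARCA2, IRAK1, PSMD10 and AKR1B10 in the si-Cont and si-SMARCA4 groups, with bars for the mean, error bars for the SD and points for the 3 libraries of each group. SMARCA4 fell from 17.3 to 3.86 FPKM and IRAK1 from 17.4 to 5.31 FPKM, while PSMD10 stood at 7.81 and 8.06 FPKM.

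The transcripts with the largest rises on the log2(FPKM + 1) scale, which draws in the changes of genes with low values, were led by interferon-stimulated genes. IFIT2 rose from 0.597 to 11.6 FPKM (log2 fold change 2.97), IFIT1 from 0.204 to 4.82 FPKM (2.27) and IFIT3 from 0.246 to 4.87 FPKM (2.23), all of the interferon-induced IFIT family. OASL rose from 0.0550 FPKM, a mean of 4 reads, to 3.08 FPKM, which is the highest ratio of mean FPKM among the 12 largest rises (55.9, against 23.6 for IFIT1 and 19.4 for IFIT2). IGFBP1, which binds insulin-like growth factors, rose from 3.05 to 18.1 FPKM, and the cytokine gene LTB from 3.0 to 15.5 FPKM. ICAM1, a cell adhesion receptor, rose from 20.1 to 73.9 FPKM, and DUSP5, a phosphatase of ERK kinases, from 1.37 to 8.71 FPKM. The other genes among the 12 largest rises were C12orf39, SCGN, RBM24 and TMEM156. Among the falls, C19orf77 fell from 11.7 to 1.37 FPKM (log2 fold change -2.43). The proteasome core subunits PSMA3 and PSMA4 fell from 22.0 to 4.79 FPKM and from 41.4 to 9.99 FPKM. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell from 11.5 to 2.22 FPKM, PPP2R4 from 13.2 to 2.48 FPKM and FLOT2 from 17.2 to 3.96 FPKM. The noncoding RNA LINC00261 fell from 30.1 to 7.79 FPKM, ABAT from 7.16 to 1.33 FPKM and the splicing factor MBNL3 from 61.8 to 18.8 FPKM. WDR83OS fell from 20.3 to 5.08 FPKM, although it overlaps WDR83 (2.57 and 2.67 FPKM) and the values do not say on which strand its reads lay.

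Over all 11123 genes tested, limma called 6227 (56.0%) at an adjusted p of 0.05, of which 2494 were higher and 3733 lower in si-SMARCA4. The median size of the called log2 changes was 0.29, and 154 genes changed at least 2-fold in FPKM + 1, 59 of them higher and 95 lower. Genes with low values can change more in FPKM than in FPKM + 1. KLF4, with an FPKM ratio of 2.77 and a log2 fold change of 0.86, is not among the 154. The groups did not overlap for 6935 genes (62.3%), where chance gives 10%. The balance of directions rested on the scaling: median-ratio scaling gave 3253 higher and 3324 lower, upper-quartile scaling 3425 and 3137, quantile normalization 3346 and 3278, and voom on recovered reads 3312 and 3351.

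Camera called 13 of 32 gene lists, 7 higher and 6 lower, and none with a correlation estimated per list, where 2 lists (YAP/TAZ targets and immediate early genes) had an unadjusted p under 0.05. Where no other count is given for a list, the count adjusted over the list alone was the same as that over all genes. In the NF-kB and inflammatory list 21 of 27 tested members rose and 2 fell, with camera adjusted p = 2.14e-08 and adjusted p = 0.638 with an estimated correlation. Beside ICAM1 and LTB, its members BIRC3, an inhibitor of apoptosis, rose from 3.71 to 8.71 FPKM and the chemokine gene IL8 from 27.4 to 81.3 FPKM. Interferon response genes followed with 13 higher and 4 lower of 22 tested members, out of 48 listed. Their camera adjusted p was 0.000319, and 0.638 with an estimated correlation. That call was lost among genes with a mean FPKM of at least 5, a filter that removed IFIT1, IFIT3 and OASL (adjusted p = 0.703, from a range of 7.59e-07 to 0.703 over the alternatives that kept the preset correlation). IFIT1, IFIT2, IFIT3 and OASL lay under 1 FPKM in si-Cont and passed the filter at a mean FPKM of 1 through their si-SMARCA4 values. Members low in both groups were left out of the 22, such as MX1 (0.0341 and 0.0883 FPKM) and OAS1 (0.0334 and 0.101 FPKM). The counts therefore do not describe the whole list. Members moved both ways, as ISG15 rose from 19.5 to 39.5 FPKM while IFITM3 fell from 68.7 to 41.3 FPKM. MX1, OAS1, ISG15 and IFITM3 were chosen after their values were seen. Endoplasmic reticulum chaperones and related factors had 16 members higher and 3 lower of 25, camera adjusted p = 0.000319 and adjusted p = 0.638 with an estimated correlation. HERPUD1 rose from 17.6 to 36.1 FPKM and DNAJB9 from 9.56 to 25.5 FPKM, but P4HB, a protein disulfide isomerase, fell from 124 to 55.3 FPKM.

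Targets of the transcriptional coactivators YAP and TAZ had 13 members higher and 3 lower of 22, camera adjusted p = 0.00037 and adjusted p = 0.638 with an estimated correlation. ANKRD1 rose from 49.2 to 145 FPKM and CYR61 from 7.97 to 13.5 FPKM. Immediate early genes had 12 members higher and 5 lower of 22, or 13 higher adjusted over the list alone, with camera adjusted p = 0.00122 and adjusted p = 0.638 with an estimated correlation. The stress factor ATF3 rose from 10.1 to 23.01 FPKM and KLF4 from 0.857 to 2.37 FPKM. The immediate early call was lost without genes whose 3′ UTR holds TGTCCA (adjusted p = 0.0686, from a range of 8.0e-05 to 0.0686 over those alternatives). Cholesterol synthesis genes rose in 13 and fell in 5 of 25 cases, camera adjusted p = 0.00194 and adjusted p = 0.638 with an estimated correlation. MSMO1 rose from 12.4 to 26.0 FPKM and SQLE, an early enzyme of the sterol branch, from 9.50 to 15.3 FPKM. Heat shock proteins had 8 members higher and 2 lower of 18, camera adjusted p = 0.0269 and adjusted p = 0.638 with an estimated correlation. BAG3 rose from 4.79 to 7.04 FPKM, whereas the co-chaperone FKBP4 fell from 27.8 to 14.9 FPKM.

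Nuclear genes of oxidative phosphorylation fell in 37 of 42 cases and rose in 0, camera adjusted p = 7.17e-07 and adjusted p = 0.638 with an estimated correlation. The succinate dehydrogenase gene SDHD_1 fell from 20.8 to 8.73 FPKM and NDUFS3, a subunit of complex I, from 14.5 to 9.62 FPKM. Fatty acid oxidation genes fell in 13 of 23 cases and rose in 0, camera adjusted p = 0.00194 and adjusted p = 0.638 with an estimated correlation. CPT1A, which controls fatty acid entry into mitochondria, fell from 12.1 to 4.99 FPKM. The median of the fatty acid oxidation list relative to all genes was -0.21, against -0.07 at a mean FPKM of at least 5 and -0.09 without genes whose 3′ UTR holds TGTCCA, CPT1A among them, where the adjusted p of 0.0457 was the highest of a range from 8.88e-06. Mitosis and G2/M genes had 36 members lower and 1 higher of 47, or 37 lower adjusted over the list alone, with camera adjusted p = 0.000308 and adjusted p = 0.638 with an estimated correlation. The topoisomerase TOP2A fell from 86.5 to 54.4 FPKM and the mitotic transcription factor FOXM1 from 19.9 to 14.1 FPKM. DNA replication and G1/S genes had 26 members lower and 5 higher of 45, camera adjusted p = 0.00246 and adjusted p = 0.638 with an estimated correlation. PCNA, the replication clamp, fell from 100.2 to 49.4 FPKM and UHRF1 from 16.9 to 9.08 FPKM. Replication-dependent histones had 21 members lower and 1 higher of 24, camera adjusted p = 0.000319 and adjusted p = 0.638 with an estimated correlation. HIST1H2AM fell from 267 to 176 FPKM, and HIST1H1D, with a mean of 12 reads in si-Cont, rose from 0.488 to 1.52 FPKM, although histone copies are near-identical and the assignment of their reads is uncertain. Ribosomal proteins had 27 members lower (34.2%, against 33.6% of all genes tested) and 0 higher of 79, or 14 lower adjusted over the list alone, with camera adjusted p = 0.00539 and adjusted p = 0.858 with an estimated correlation. RPL10 fell from 89.4 to 50.9 FPKM and RPL34 from 55.9 to 41.6 FPKM, and both hold one of the 7-base 3′ UTR sequences whose carriers were lower on average. Quantile normalization turned the direction of the ribosomal list (median 0.02 relative to all genes, adjusted p = 0.277, from a range of 2.55e-07 to 0.277 over those alternatives), and the share of reads over genes was lower in si-SMARCA4, at 61.6% against 65.4%.

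**Figure D2:**
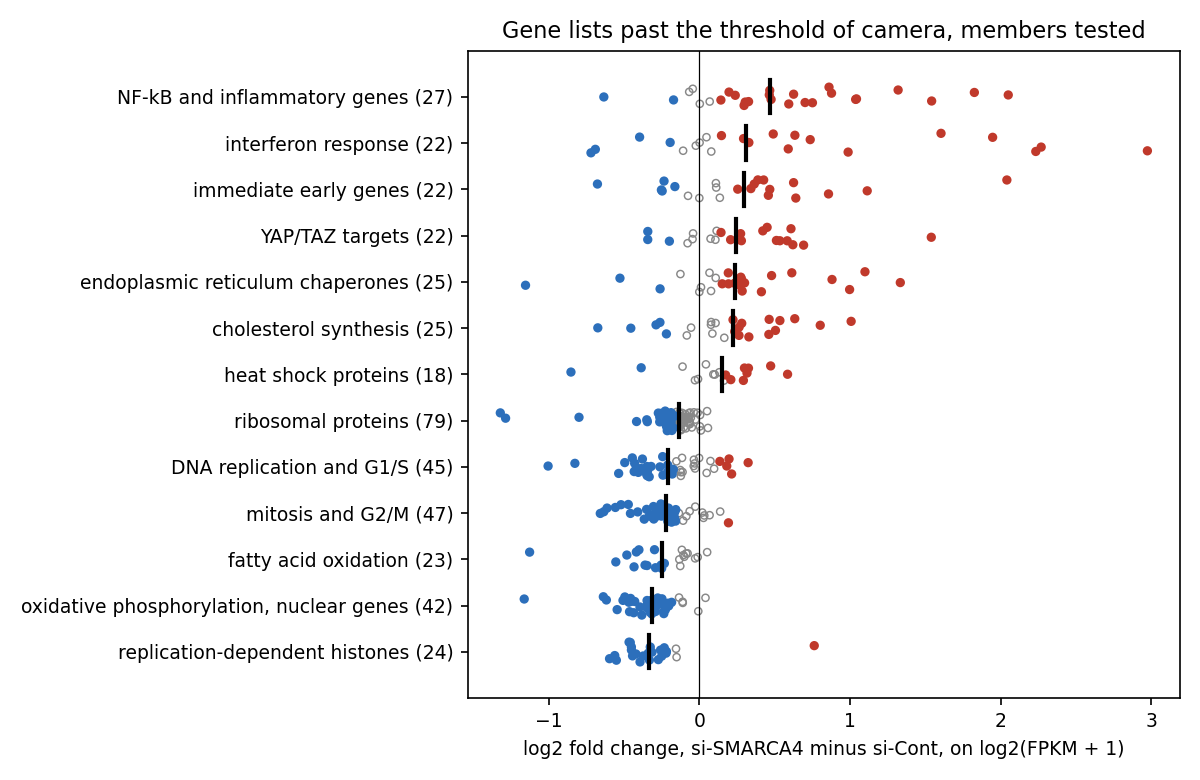
Log2 fold change (si-SMARCA4 minus si-Cont) of each tested member of the 13 gene lists past the camera threshold, with filled points for genes at an adjusted p under 0.05 and a black bar for each list's median. NF-kB and inflammatory genes had 21 of 27 members higher, and nuclear genes of oxidative phosphorylation had 37 of 42 lower; the ribosomal list turned direction under quantile normalization.

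Lists chosen for the liver and for the target complex did not pass in the fit described. SWI/SNF subunits had 2 members higher and 11 lower of 22, or 3 higher adjusted over the list alone (camera adjusted p = 0.0902, from 0.00485 with no filter on low values to 0.354 over the alternatives). SMARCC1 and SMARCD1, core subunits, fell from 10.4 to 7.80 FPKM and from 16.4 to 12.9 FPKM. Hepatocyte transcription factors had 3 members higher and 13 lower of 24 (camera adjusted p = 0.083, from 0.00581 with no filter to 0.329 over the alternatives). HNF4A, a central regulator of hepatocyte genes, fell from 40.6 to 26.0 FPKM and GATA4 from 9.32 to 6.75 FPKM. Hepatocyte secreted proteins had 12 members higher and 16 lower of 36, or 15 and 17 adjusted over the list alone (camera adjusted p = 0.956), and their median of -0.15 was opposite in sign to the direction of camera. The coagulation factor gene F7 fell from 12.3 to 5.35 FPKM, the fetal liver protein gene AFP from 213 to 116 FPKM and the fibrinogen gene FGG from 37.2 to 20.4 FPKM, while CFB_2, which overlaps C2 so that the assignment of its reads is uncertain, rose from 3.68 to 7.05 FPKM. Targets of the oxidative stress factor NRF2 had 7 members higher and 7 lower of 20 (camera adjusted p = 0.582), with HMOX1 higher, from 12.6 to 22.5 FPKM.

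Of 17 immune cell markers, 15 lay under 1 FPKM in si-SMARCA4 and were not in the limma fit. Of the 2 that were tested, LYZ stood at 16.4 and 16.0 FPKM and CD68 fell from 17.2 to 10.6 FPKM. Endothelial markers had 0 tested members, and the highest, ESAM, stood at 0.463 and 0.727 FPKM. Of the fibroblast and stellate cell markers, LUM rose from 7.25 to 11.4 FPKM and PDGFRA fell from 1.99 to 1.72 FPKM. Cholangiocyte markers had 1 member higher and 3 lower of 6 (camera adjusted p = 0.327), with KRT19 at 50.9 and 38.1 FPKM.

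A search of 3′ UTRs, chosen after the data were seen, found 7-base sequences whose carriers were lower on average in si-SMARCA4, with many carriers not called and some higher. CTGTCCA had the lowest score of the 16152 sequences, at -14.0 over 1464 genes, followed by TGTCCAA at -13.9 over 1093 genes and ATGTCCA at -9.84. The highest size of a score in 100 shuffles was 5.07, and 17 sequences exceeded it, 13 in lower and 4 in higher genes. These are not 17 separate findings, because many of the sequences overlap. CTGTCCA, TGTCCAA and ATGTCCA all hold TGTCCA, and CACTTTA and GCACTTT, in higher genes, share CACTTT. Genes with the 8-base sequence CTGTCCAA were called lower in 53.2% of 297 cases, genes with only a 7-base part in 43.7% of 1793, genes with only TGTCCA in 33.2% of 1600 and genes with none in 30.6% of 6592. In the same order, 15.2%, 17.7%, 22.9% and 24.7% were called higher. A 7-base site was held by 50 of the 90 searched genes that were at least 2-fold lower (55.6%) and by 20.02% of the other genes, and by 4 of the 55 that were at least 2-fold higher (7.27%). These shares come from the fold changes on which the sequences were chosen, so they are no separate test. With the genes parted at random, each part gave the same 2 sequences, and 8-base genes of the other part averaged -0.222 and -0.272 relative to genes with none. Of the 10 searched genes among the 12 largest falls, SMARCA4 left out, 9 held a site, namely IRAK1, PPP2R4, PSMA3, PCK2, PSMA4, FLOT2, ABAT, WDR83OS and MBNL3, and C19orf77 did not. None of the 12 largest rises held one (0 of 12). Sites were also found in genes that fell less, such as SDHD_1, CPT1A, FOXM1, P4HB and HNF4A, and in GCLM, which rose from 4.07 to 6.23 FPKM. In IRAK1 the sequence TGTCCAA lay on chromosome X from 154010639 to 154010645 (GRCh38, reverse strand), in the 3′ UTR of 2 of its 4 coding transcripts. In SMARCA4 the 8-base sequence lay in the coding sequence of 18 of 18 coding transcripts, on chromosome 19 from 11018961 to 11018968 (forward strand).

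**Figure D3:**
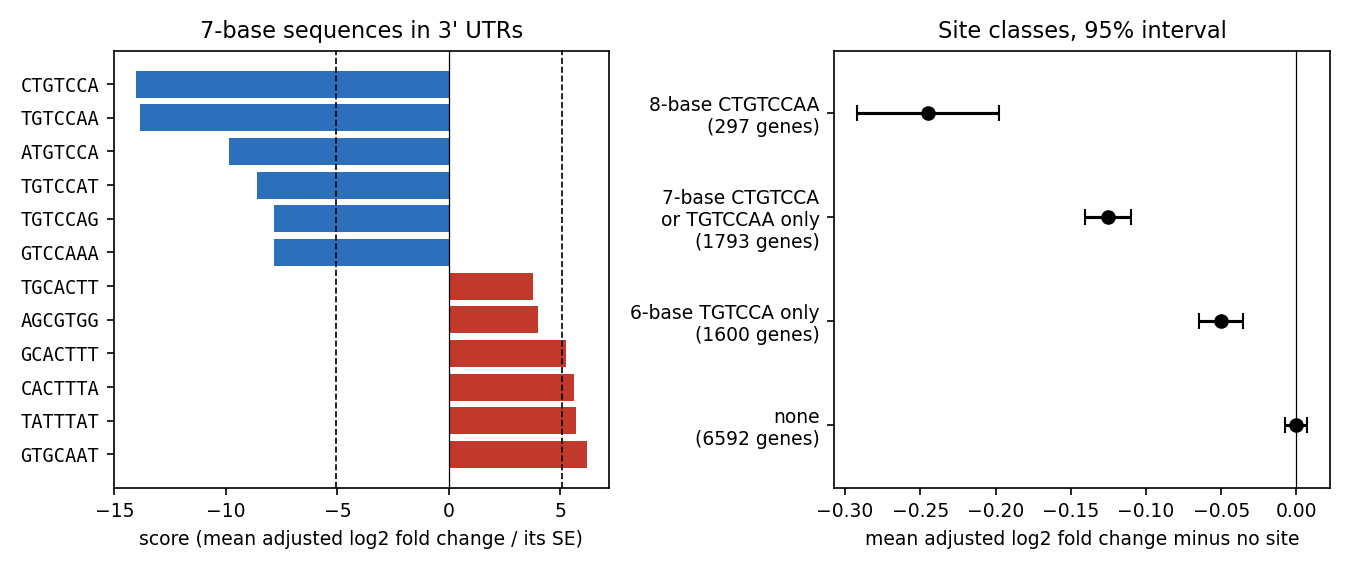
Left, scores of the 7-base 3′ UTR sequences with the 6 lowest and 6 highest values, with dashed lines at the highest size in 100 shuffles (5.07). Right, mean adjusted log2 fold change of genes by site class relative to genes with no site, with 95% intervals; the 8-base class lay at -0.245 and the 6-base class at -0.0501.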

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

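The fits with voom, with the length and GC trend removed, and without genes whose 3′ UTR holds TGTCCA were chosen only after the result was seen. Over all alternatives run, named genes other than SMARCA4 kept their side of the threshold in all 1725 comparisons where they were tested. They kept their sign in all but 3, all of PSMD10, which was not past it, and IRAK1 ranged from -1.69 to -1.12. Comparisons in which a filter removed the gene are not counted. Apart from the genes of interest, these genes were picked from the same data for large changes or small p. Their calls could therefore hardly change. List comparisons gave 677 with the side of the threshold kept, 40 newly past it, 16 no longer past it and 1 where the direction of a called list turned. List medians relative to all genes changed sign in 19 of 734 comparisons, 2 of them of called lists, the ribosomal one and the interferon one at a mean FPKM of at least 5 (-0.000953). A filter at a mean FPKM of 5 gave 3683 genes (1387 higher and 2296 lower) because fewer genes were tested (6120). Leaving out genes that hold TGTCCA gave 3882 of 7431 genes tested (52.2%, against 56.0% with these genes kept). Of those calls 1698 were higher and 2184 lower, so that 43.7% were higher, against 40.1% with these genes kept. The fit without them has no value for SMARCA4 or IRAK1, whose 3′ UTRs hold TGTCCA. Asking for 2-fold changes in FPKM + 1 gave 154 genes, 59 higher and 95 lower. Lists past the threshold numbered 20 with no filter (the cause was not tested), 0 with an estimated correlation and 25 with fry, which tests each list alone and not against other genes. Quantile normalization put the ribosomal list at 0.0192 relative to all genes (the cause was not tested). Leaving out each library in turn gave 5181 to 7140 genes (2026 to 2635 higher and 3073 to 4505 lower), 13 to 16 lists and a SMARCA4 log2 fold change of -1.97 to -1.82, with the highest count, 7140, without si-Cont replicate 2. The replicate block gave 6760 genes and changed no list call. Read depth limits AKR1B10 (14 to 22 reads) and OASL in si-Cont (4 reads).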

Other observations

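The search of 3′ UTR sequences, the tests of 3′ UTR length and base composition and of chance among 7-base sequences, the choice of these sequences on parts of the genes, and the removal of the length and GC trend were chosen only after the result was seen. The gene lists not yet described did not pass the threshold. Targets of p53 had 11 members higher and 7 lower of 24, or 12 higher adjusted over the list alone (camera adjusted p = 0.0554), with GADD45A higher, from 10.2 to 24.1 FPKM, and CDKN1A lower, from 9.43 to 4.60 FPKM, both chosen after their values were seen. Wnt and beta-catenin targets had 0 members higher and 8 lower of 14 (camera adjusted p = 0.0554), and ATF4 targets 5 higher and 18 lower of 33 (0.083). Fatty acid synthesis genes had 2 members higher and 8 lower of 14 (0.0902), and hepatocyte metabolism genes 5 and 13 of 19 (0.141). Epithelial junction genes had 4 members higher and 12 lower of 23, or 13 lower adjusted over the list alone (0.119). Extracellular matrix and mesenchymal genes had 11 members higher and 11 lower of 26 (0.141), acute phase genes 6 and 4 of 13 (0.166), apoptosis regulators 6 and 5 of 22 (0.543) and genes of glycolysis and hypoxia 9 and 14 of 30 (0.693). Proteasome subunits had 1 member higher and 11 lower of 31, or 0 and 10 adjusted over the list alone (0.0902). Ribosome biogenesis genes had 6 members higher and 8 lower of 31, or 5 and 8 adjusted over the list alone (0.839), other chromatin remodellers 5 and 9 of 28 (0.956), and mitochondrially encoded genes 0 and 1 of 13, or 0 and 0 adjusted over the list alone (0.956). Several of these calls changed with the processing: the lowest adjusted p over the alternatives was 0.0307 for p53 targets, 0.00631 for Wnt and beta-catenin targets, 0.00616 for ATF4 targets, 0.0101 for fatty acid synthesis, 0.0185 for hepatocyte metabolism, 0.0153 for epithelial junctions and 0.00355 for proteasome subunits. Leaving out 1 library took 4 of these lists past the threshold. Wnt and beta-catenin targets passed without si-Cont replicate 1 (adjusted p = 0.0331), si-Cont replicate 3 (0.0477) or si-SMARCA4 replicate 3 (0.046), and p53 targets without si-Cont replicate 1 (0.0404) or si-SMARCA4 replicate 3 (0.0385). Fatty acid synthesis genes passed without si-Cont replicate 1 (0.0408) and proteasome subunits without si-Cont replicate 2 (0.0036).

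Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one (6227), namely the real one itself, and the highest of the others gave 1. The 3 other splits that also part every pair gave at most 0. With 10 splits no share can fall under 0.1.

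Genes whose 3′ UTR holds TGTCCAA or CTGTCCA, IRAK1 among them, were lower on average in si-SMARCA4, where 942 of 2090 (45.1%) were called lower and 363 (17.4%) higher. The length and base composition of 3′ UTRs are argued against as the whole cause, since the difference was -0.133 (SE 0.00824) with both regressed out, and so is chance among 7-base sequences, since shuffles reached 5.07 and the observed score 14.03 in size, and the choice of the sequences on the same genes, since 8-base genes not used for the choice averaged -0.222 (SE 0.0288) in the part with the smaller difference. On the genes used for the choice, genes with the 8-base sequence averaged -0.245 relative to genes with none. There, genes with a site only in the 3′ UTR averaged -0.139 against -0.075 for a site only in the coding sequence. In the parts not used for the choice, these were -0.121 against -0.070 and -0.156 against -0.080. Pairing of an siRNA seed would give this order, although the fold changes were not adjusted for the length of the coding sequence. A candidate explanation is that part of these falls, that of IRAK1 included, may come from the siRNA pairing with 3′ UTRs and not from the loss of SMARCA4, whose own coding sequence holds the 8 bases, as do 49 of 412 genes (11.9%) with coding sequences of 4000 to 6000 bases. The siRNA sequence is not given in the sources used here, and regulation of any 1 of these genes by SMARCA4 stays open as untested.

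In si-SMARCA4, 21 of 27 tested NF-kB and inflammatory genes (38 listed) and 13 of 22 tested interferon response genes (48 listed) rose. In these lists 2 and 4 fell. Both lists had adjusted p = 0.638 with an estimated correlation, and the interferon list had 0.703 at a mean FPKM of at least 5. Immune cells in the cultures are argued against as the source, since the largest rise of an immune marker, ITGAM, was 0.240 FPKM. A response to the siRNA duplex cannot be told apart from a response to the loss of SMARCA4, because the design holds 1 group with siRNA against SMARCA4. Repression by a seed of the control siRNA also stays open. GTGCAAT, the sequence with the highest score (6.19), was held by 17.6% of 34 risen members and 13.3% of other genes (Fisher's exact p = 0.445). TATTTAT (5.72), CACTTTA (5.61) and GCACTTT (5.25) also exceeded the shuffles in higher genes and were not examined in this way. Whether any of these is a seed of the control siRNA is not known, because its sequence is not given.

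In si-SMARCA4, 37 of 42 respiratory chain genes, 21 of 24 histone genes and 27 of 79 ribosomal protein genes (14 adjusted over the list alone; 34.2%, against 33.6% of all genes tested) were lower, with adjusted p = 0.638, 0.638 and 0.858 with an estimated correlation. With the trend of gene length and GC content removed, the respiratory list kept 99.9% of its median relative to all genes and the ribosomal list 65.6%. This argues against that trend as the whole cause. Only 16 of 24 histone genes had a length and GC value. Those 16 kept 90.0% (95% interval 64.6 to 109), which argues against the trend as the whole cause for them. The other histone genes could not be tested. A smaller share of reads over genes in si-SMARCA4, taken as 1 factor per library, is argued against for the respiratory and histone lists. Their medians under median-ratio scaling were -0.260 and -0.281, against -0.312 and -0.335 without it. Such scaling moves all genes of a library by the same factor, so a loss of reads that differs between genes was not tested. For the ribosomal list the median under median-ratio scaling was -0.0838 (camera adjusted p = 0.00218 at the preset correlation), against -0.137 without it. That 1 factor per library thus did not take the fall away. Quantile normalization, which moves genes of a library by different amounts, turned the direction. For this list a loss of reads that differs between genes cannot be told apart from lower levels of these genes. A change that follows from the loss of SMARCA4 stays open for all 3 lists, as untested.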
